A study of Mus musculus with 6 samples.

How the data were processed

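Total RNA from pooled rhombomere 4 segments of E10.5 mouse embryos was hybridised to Affymetrix GeneChip 430A arrays, 3 arrays from wild-type and 3 from Hoxb1 mutant pools. The deposited table holds 1 intensity per probe set and array on a linear scale, as the range of the values shows. The submitters' processing notes name the tool affy, with no version. The expression algorithm, the background correction and detection calls are not given in the sources used here. The values show a scaling step: on each array the mean of all 22690 deposited intensities, with 2% trimmed at each end, was 500.0. No further normalization was applied. A scaling by 1 factor per array leaves differences in the shape of the distribution, and the median log2 difference between groups was -0.02 over all probe sets, -0.05 among those below the median intensity and 0.04 among the brightest 10%. Bright and dim genes are therefore offset slightly in opposite directions.

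The 64 Affymetrix control probe sets were left out of the tests, and the other 22626 were tested. Of these, 20380 name 1 gene, of 12393 genes in all, and 691 are listed with several genes and were not named. Symbols came from the platform annotation and were updated through the Entrez identifier in a RefSeq gene table of assembly GRCm38.p6 where it held it, for 20351 probe sets. Coordinates are not printed, since the build behind the array annotation is not given in the sources used here. Bacterial control probe sets, 27 in number, served as the measure of background. A fold is given as a lower bound where every array of 1 group lay at or below their 95th percentile; it is the difference of mean log2 intensities with arrays below that percentile set to it.

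Intensities were transformed to log2(intensity + 16). Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend, 2-sided, all 6 arrays, no covariate), with Benjamini-Hochberg adjustment over all probe sets tested and a threshold of 0.05. Values are mean ± SD of 3 arrays, and standard errors are those of the moderated fit. For gene lists, the probe set with the highest mean stood for each gene. The lists were compared with all other genes by limma's camera with a preset correlation of 0.01, adjusted over 35 lists. The list shift is the mean log2 difference of the members minus that of other genes. Each list was also tested with an estimated correlation and with fry, which tests a list against no change rather than against other genes. It was further set against 10000 random lists matched on mean intensity, and compared by an exact permutation of its array scores.

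The lists were fixed before the data were examined. They covered Hox genes, Hox cofactors, rhombomere 4 and Hoxb1-dependent genes, other rhombomeres and the isthmus, cranial motor neurons, facial neuron migration and planar polarity, ventral and dorsal patterning, serotonergic, noradrenergic and visceral, and GABAergic, glutamatergic and glycinergic neurons, pan-neuronal genes, neural progenitors and the glial lineage. Others held markers of cells outside the neural tube, genes of the cell cycle, apoptosis, stress, hypoxia and signalling pathways, sex-linked genes and the neighbours of Hoxb1. The genes named were Hoxb1, up to 8 genes per direction of smallest p where fewer passed the threshold, up to 3 members of smallest p of each list, and every measured member of the rhombomere 4 list. Members outside that rule (Isl2, Mnx1, Slc18a3, Celsr2, Sox21, Tpi1, Pkm, Pgk1, Uty and further probe sets of named genes) were chosen after their values were seen.

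Alternatives fixed in advance were quantile normalization, centring on array medians, leaving out the dimmest 33.3% of probe sets, eBayes with trend and robust settings, array weights, the replicate number as a block, leaving out each array, pseudocounts of 1 and 64, 1 probe set per gene, other thresholds and other list tests. The 18S signal as a covariate, and leaving out the 2 wild-type arrays with high 18S signal, were added after seeing the data. The limma step was tested on simulated data, 10 draws of 22626 probe sets with the spread of these arrays. It called 48.8%, 86.4%, 95.0% and 99.4% of probe sets changed by log2 differences of 1, 2, 3 and 4, and 82 of 224260 unchanged ones. Probe sets of all sizes were changed together in each draw, 500 per size over the 10 draws. The estimated spread of each probe set was taken as its true spread. The list step called 20 of 20 simulated lists of 20 genes shifted by -0.3, and 1 of 600 unshifted lists, in data without correlation between genes.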

Results

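Transcript levels were measured in the hindbrain of E10.5 mouse embryos, in rhombomere 4, the segment whose identity Hoxb1 specifies and from which the facial motor neurons arise. The comparison set Hoxb1 mutant embryos against wild-type embryos, and asks which transcripts of this segment depend on Hoxb1. Each group held 3 pools of dissected segments, stated by the submitters to be independent biological replicates. Per the labels, the tissue was mainly rhombomere 4 and also held branchial arch tissue around it. Each pool was hybridised to 1 Affymetrix mouse array, which gave 22690 probe set intensities. The median intensity of the probe sets tested lay between 187 and 214 on the 6 arrays. Across probe sets, arrays correlated at 0.976 to 0.984 within a group and at 0.973 to 0.983 between groups, and 0 pairs of arrays held identical values. Control probe sets for bacterial transcripts, which have no mouse target, had a median intensity of 12.7, a 95th percentile of 61.5 and a highest value of 122. Where every array of 1 group lay at or below 61.5, a fold is given as a lower bound, set against 61.5. Intensities are given as mean ± SD (n = 3), and differences as mutant minus wild type on the scale of log2(intensity + 16), which understates the change of dim probe sets. The number of arrays limits the precision, and the median standard error of a log2 difference was 0.16.

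Hoxb1, the targeted gene, gave 436 ± 134 in wild type and 48.7 ± 12.8 in mutants with its only probe set (1453501_at), at least 6.88-fold higher in wild type. The wild-type arrays gave 341, 378 and 588, and the mutant arrays lay between 35.3 and 60.8, within the range of the bacterial controls. The fitted log2 difference of the measured values was -2.78 (SE 0.24), with a mutant level that cannot be told from background. In limma the adjusted p was 0.0695, which missed the threshold of 0.05. Over 15 alternative settings, 1 of them chosen after seeing the data, the adjusted p ran from 0.0114 to 0.638, and it passed the threshold in 4 of them. Another, also chosen after seeing the data, gave 0.743 without wild-type replicates 2 and 3, where 1 wild-type array is left and is assumed to vary like the mutants. Whether this probe set lies in the deleted part of the gene is not given in the sources used here, so its loss of signal checks the labels only if it does.

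**Figure D1:**
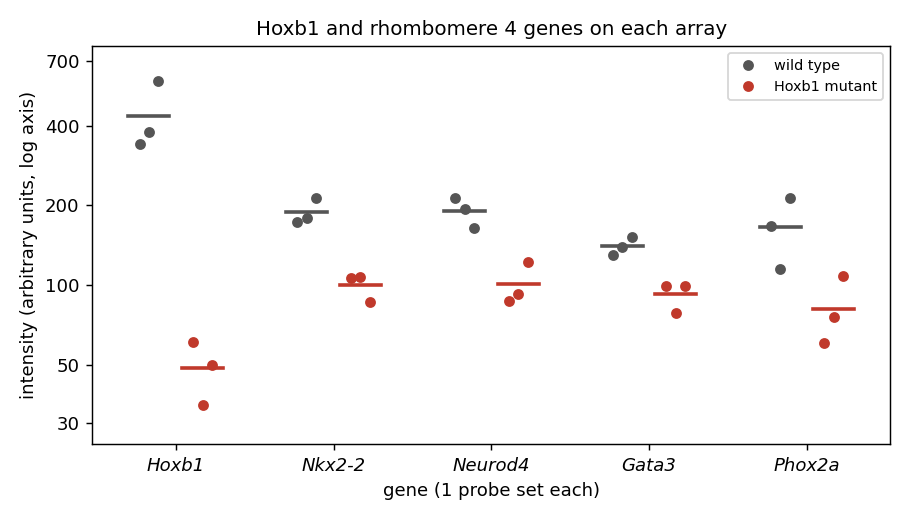
Intensities (arbitrary units, log axis) of Hoxb1 and of the 4 genes of smallest p in the rhombomere 4 list on each of the 3 wild-type (grey) and 3 Hoxb1 mutant (red) arrays, with lines at the group means. In all of these genes every mutant array lay below every wild-type array, with Hoxb1 means of 436 and 48.7.

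Beside Hoxb1, the probe sets of smallest p belonged to Paip1, a partner of the poly(A)-binding protein in translation, Retsat, which encodes retinol saturase, and Efcab2. The Paip1 probe set 1425521_at gave 37.3 ± 9.47 in wild type and 345 ± 93.1 in mutants, at least 5.48-fold higher in mutants. The Retsat probe set 1424716_at gave 6.24 ± 1.33 and 41.8 ± 2.74, and the Efcab2 probe set 1449884_at gave 3.67 ± 2.07 and 40.2 ± 4.52, both below the bacterial 95th percentile on all 6 arrays. Each had a limma adjusted p of 0.0695, and 0 of the 22626 probe sets tested passed 0.05. An unadjusted p under 0.05 was reached by 1303 probe sets, against 1131 expected by chance, of which 425 were higher and 878 lower in mutants. Without mutant replicate 1 this number was 1975, and with array weights 2093. The groups did not overlap in 11.96% of probe sets, where chance gives 10%. In simulated data of the same size and spread, limma called 48.8% of probe sets changed by a log2 difference of 1, and 86.4% of those changed by 2. There, 500 probe sets were changed at each size over 10 draws. Many changes at once ease the adjusted threshold, so these shares do not carry over to data in which few probe sets change.

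Pttg1, which encodes securin, a regulator of sister chromatid separation, was the brightest of the 8 genes of smallest p that were higher in mutants. Its probe sets 1424105_a_at and 1438390_s_at gave 713 ± 34.3 and 3600.5 ± 123 in wild type and 1272 ± 82.9 and 6048 ± 169 in mutants, log2 differences of 0.82 and 0.75 (SE 0.11 and 0.10). A dimmer probe set of Pttg1 had a log2 difference of -0.25 (SE 0.25). Stk17b, a kinase of the death-associated family, gave 33.5 ± 8.75 and 109 ± 5.95, and Efcab7 gave 135 ± 29.4 and 312 ± 14.3. Ttc39d and Magea7-ps completed the 8. The 8 genes of smallest p that were lower in mutants were Hoxb1, Mfap5, Fxyd2, Shfl, Tbx15, Gm34703, Lmbr1 and Ccr2. Tbx15, a T-box gene of the skeletal and dermal mesenchyme, gave 81.0 ± 15.6 in wild type and 14.7 ± 8.65 in mutants. Mfap5, a protein of elastic microfibrils, gave 51.3 ± 4.19 and 14.7 ± 3.47. All of these missed the threshold over all probe sets, with limma adjusted p of 0.0695 to 0.428.

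Most of these probe sets were dim, and other probe sets of the same genes mostly differed from them. Of the 16 genes, 11 had group means below the brightest bacterial control value in both groups. Another probe set was present for 10 of the genes, and in 2 of them, Paip1 and Pttg1, another one had an unadjusted p under 0.05 in the same direction. In Fxyd2 another one, at 29.6 ± 11.7 and 47.2 ± 5.87, had one in the opposite direction. The other probe set of Paip1 gave 948 ± 58.7 and 1173.5 ± 86.2, a log2 difference of 0.30 (SE 0.12). Those of Retsat and Efcab2 gave log2 differences of -0.06 (SE 0.19) and -0.07 (SE 0.18), and that of Tbx15 gave -0.27 (SE 0.16).

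**Figure D2:**
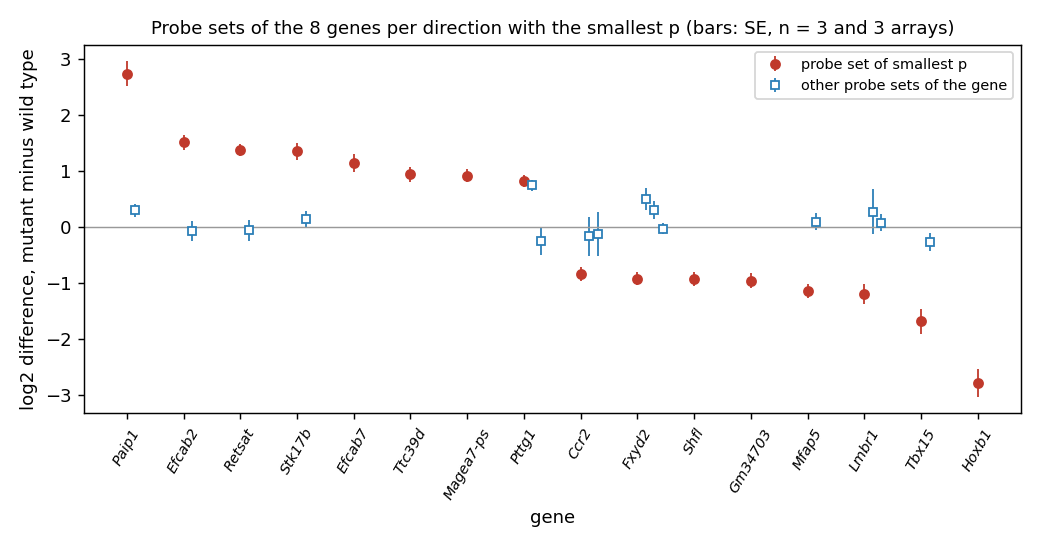
Log2 differences, mutant minus wild type, of all probe sets of the 8 genes per direction with the smallest p. Red points mark the probe set of smallest p, in 11 of the 16 genes with both means below the brightest bacterial control, blue squares the other probe sets of the same gene, and bars the standard error (n = 3 arrays per group). The red point of Paip1 lies at 2.74 in the fit and its blue square at 0.30, whereas 1 blue square of Pttg1 lies at 0.75, next to its red point at 0.82.

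Gene groups were compared through 35 lists fixed before the data were examined, each tested against all other measured genes with limma's camera. Of these, 5 were lower and 1 higher in mutants at an adjusted p under 0.05. They were the rhombomere 4 and Hoxb1-dependent genes, cranial motor neurons, facial neuron migration and planar polarity, pan-neuronal genes and neural progenitors, all lower, and hypoxia and glycolysis, higher. None of the 6 kept its call with an estimated correlation, where the lowest camera adjusted p was 0.425. None passed in fry either, where the lowest adjusted p was 0.281, but fry tests a list against no change rather than against other genes. The probe sets for 18S ribosomal RNA set wild-type replicates 2 and 3 apart, with mean log2 signals of 12.1 and 11.3, against 6.36 to 7.03 on the other 4 arrays. With that signal as a covariate, an alternative chosen after seeing the data, 0 lists passed, and the 6 shifts kept their sign at 63.99% to 95.3% of their size. In the exact permutation of array scores, 4 of the 6 lists gave 0.1, the smallest p that 3 against 3 arrays allow, neural progenitors 0.2 and pan-neuronal genes 0.5. The retinoic acid and hedgehog lists, which did not pass in camera, also gave 0.1, so this value does not set the called lists apart. Among 10000 random lists matched on mean intensity, the medians of the 5 lower lists lay at percentiles of 0 to 0.79, and that of hypoxia and glycolysis at 100. The random lists draw genes singly from these same arrays. Their percentiles therefore leave out the correlation between members and the spread between arrays, and do not test a difference between the groups. The ratios of 3′ to 5′ signal were alike on all arrays, at 0.761 to 0.815 for Gapdh and 1.03 to 1.13 for Actb.

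The rhombomere 4 and Hoxb1-dependent list was lower in mutants as a group, although its members Hoxa2, Epha2 and Fgf3 stayed near wild type. The list lay -0.32 log2 units from other genes, with camera adjusted p = 0.00175, and adjusted p = 0.425 with an estimated correlation. Of the 16 measured members of the list, drawn from background knowledge of Hoxb1 and this segment, 13 had a lower mean in mutants and 0 passed over all probe sets. Adjusted over the list alone, 4 fell and 0 rose. Nkx2-2, which marks ventral progenitors of visceral motor neurons, fell from 188 ± 21.3 to 99.9 ± 11.9 (log2 difference -0.82, SE 0.14). Neurod4, a proneural factor, fell from 190 ± 24.6 to 101 ± 19.2 (-0.83, SE 0.16), while its dimmer probe set lay below the bacterial 95th percentile on all arrays. Gata3, a transcription factor of ventral hindbrain neurons, fell from 140 ± 10.7 to 92.1 ± 11.99 (-0.53, SE 0.13). Phox2a, which acts in branchiomotor and noradrenergic neurons, fell from 165 ± 48.7 to 81.4 ± 24.6 (-0.89, SE 0.26). Their limma p adjusted over the list alone were 0.0106, 0.0129, 0.0280 and 0.0474.

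The other members of the list missed that test. Nkx6-1 gave 151 ± 66.6 in wild type and 62.9 ± 47.9 in mutants, with overlapping groups. Gata2 gave 413 ± 29.1 and 343 ± 54.1, Hoxb2 gave 1370.5 ± 46.3 and 1149.9 ± 149, Crabp1 gave 6094 ± 394 and 5356 ± 647, and Isl1 gave 1692 ± 124 and 1508 ± 65.7. Tbx20 had a log2 difference of -0.26 (SE 0.17), and Lmx1b gave 31.7 ± 30.7 and 15.7 ± 6.48, with 1 of the 6 arrays above the bacterial 95th percentile. Ret, Epha2 and Hoxa2 had log2 differences of -0.04, 0.04 and 0.00 (SE 0.24, 0.24 and 0.15), and Fgf3 and Ptf1a of 0.11 and 0.17 (SE 0.18 and 0.19). Second probe sets of Tbx20, Isl1, Gata2 and Fgf3 gave -0.01, -0.08, -0.60 and 0.14 (SE 0.23, 0.12, 0.26 and 0.36). Those of Gata2 and Fgf3 were dim, with mutant means of 34.5 and 29.5. In the list score every mutant array lay below every wild-type array (exact permutation p = 0.1). The call was kept without each array in turn, and with the 18S covariate the shift was -0.23 with adjusted p = 0.156. Of the 16 members, 15 also stand in another list.

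The Hox genes as a group did not pass the threshold, with a list shift of -0.01 and camera adjusted p = 0.827 over 26 genes. Hoxb3, expressed behind rhombomere 4, gave 189 ± 34.4 in wild type and 110 ± 19.9 in mutants, Hoxa3 gave 201 ± 25.7 and 148 ± 23.5, and Hoxa5 gave 21.1 ± 10.97 and 39.3 ± 0.761, none past the test over the list alone. Among 8 genes for Hox cofactors, the TALE homeobox gene Meis3 fell from 398 ± 54.7 to 237 ± 35.4 (log2 difference -0.71, SE 0.16; limma p adjusted over the list alone 0.0270). Pbx2 and Pbx3 gave -0.23 (SE 0.12) and 0.15 (SE 0.13), and the list had a shift of -0.07 with camera adjusted p = 0.456. Markers of other rhombomeres and the isthmus had a shift of -0.04 (adjusted p = 0.613), with En2 at 32.3 ± 8.05 and 15.9 ± 8.31, within the range of the bacterial controls.

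Motor neuron genes were lower in mutants as a group, with 17 of 20 members below wild type. The list shift was -0.25 (camera adjusted p = 0.00861, and adjusted p = 0.605 with an estimated correlation). Tbx2 gave 332 ± 48.0 in wild type and 231 ± 28.2 in mutants, and Lhx3, a LIM homeobox gene of motor neurons, gave 217 ± 28.0 and 140 ± 42.5. The general motor neuron gene Isl2 had a log2 difference of -0.09 (SE 0.14), and Slc18a3, the vesicular acetylcholine transporter, had -0.20 (SE 0.16), while Mnx1, at 40.2 ± 9.15 and 39.6 ± 21.1, lay below the bacterial 95th percentile on all arrays. Adjusted over the list alone, 0 members passed. The call was lost without wild-type replicate 3 (adjusted p = 0.0666), without mutant replicate 3 (0.160), with members of 1 list only (shift -0.16, adjusted p = 0.142) and with the 18S covariate (shift -0.19, adjusted p = 0.156).

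In the list of facial neuron migration and planar polarity genes, 21 of 32 members were lower in mutants. The list shift was -0.17 (camera adjusted p = 0.0294, and adjusted p = 0.605 with an estimated correlation). Slit1, a secreted axon guidance cue, fell from 163 ± 36.3 to 48.1 ± 20.7 (log2 difference -1.51, SE 0.26; limma p adjusted over the list alone 0.0241), and was the member past that test, with 1 of its 3 mutant arrays above the bacterial 95th percentile. Slit3 gave 129 ± 57.5 and 42.7 ± 25.2, with every mutant array below the bacterial 95th percentile. The polarity gene Celsr2 gave 795 ± 123 and 584 ± 73.4. Vldlr, a reelin receptor, gave 154 ± 9.45 and 215 ± 20.6, and in a dimmer probe set, in the other direction, 60.3 ± 12.01 and 29.6 ± 6.20. The list passed neither without wild-type replicate 3 (0.197) nor without mutant replicate 3 (0.160), and other settings that ended it were the low filter (shift -0.09, adjusted p = 0.0626), array weights (-0.15, 0.0829), members of 1 list only (-0.19, 0.0503) and the 18S covariate (-0.11, 0.455).

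Genes of neurons and of neural progenitors were also lower as groups in camera, although array scores of the groups overlapped in both lists, with exact permutation p of 0.5 and 0.2. The shifts were -0.14 for pan-neuronal genes (camera adjusted p = 0.00943, and adjusted p = 0.605 with an estimated correlation) and -0.13 for progenitors (adjusted p = 0.0225, and adjusted p = 0.605 with an estimated correlation). Among 32 pan-neuronal genes 26 were lower, among them Ebf1 at 430 ± 39.1 and 327 ± 60.6 and Ncam1 at 741 ± 148 and 558 ± 88.7. Among 23 progenitor genes 18 were lower. The SoxB genes Sox3 and Sox21 gave 1059 ± 275 and 527 ± 115 in wild type and 608 ± 52.0 and 348 ± 41.4 in mutants, and the Notch ligand Jag1, in the other direction, gave 200 ± 67.1 and 339 ± 30.1. Adjusted over either list alone, 0 members passed. Without wild-type replicate 3 the shifts were -0.06 and -0.04 (adjusted p = 0.477 and 0.301), without mutant replicate 3 they were -0.04 and -0.14 (0.546 and 0.160), and with the 18S covariate -0.12 and -0.11 (0.156 for both). The progenitor list also missed the threshold without mutant replicate 1 (shift -0.10, adjusted p = 0.105) and with array weights (-0.07, 0.155), and the pan-neuronal list with the mean of all probe sets of a gene (-0.10, 0.117) and with members of 1 list only (-0.12, 0.0503).

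**Figure D3:**
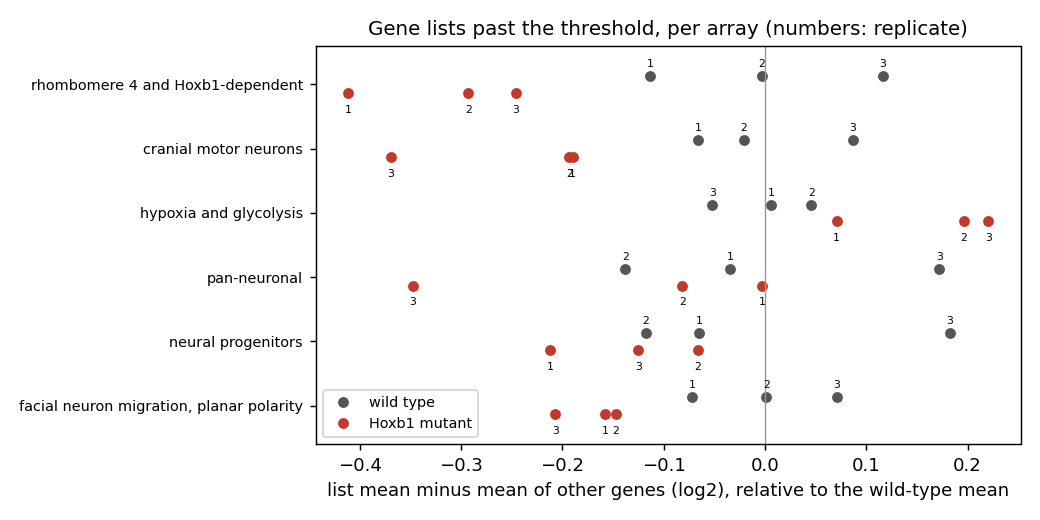
Scores of the 6 gene lists past the threshold on each wild-type (grey) and Hoxb1 mutant (red) array, as the list mean minus the mean of other genes in log2 units, relative to the wild-type mean. The numbers give the replicate. For the rhombomere 4 list the mutant arrays lie at -0.41, -0.29 and -0.25, below all wild-type arrays, whereas in the pan-neuronal and progenitor lists the groups overlap.

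Other neuronal lists did not pass. Serotonergic genes had a shift of -0.19 (camera adjusted p = 0.133), with Gata3 past the test over the list alone. Noradrenergic and visceral genes had -0.14 (0.542), and GABAergic, glutamatergic and glycinergic genes -0.11 (0.127). The latter list passed under 1 of 20 settings, the low filter (0.0287), and without wild-type replicate 3 its shift turned to 0.0046 (0.654). Ventral progenitor patterning had -0.08 (0.440), with Nkx2-2 past the test over the list alone, as it was among the hedgehog genes. Dorsal progenitors and interneurons had -0.06 (0.413), with Lmo1 at 373 ± 24.0 in wild type and 270.3 ± 39.4 in mutants. The glial lineage list had a shift of 0.00 and adjusted p = 0.781, and its mean shift and its test differed in sign. Its member Sox10, a crest and oligodendrocyte factor, gave 460.3 ± 36.2 and 345 ± 33.1.

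Genes of hypoxia and glycolysis were higher in mutants as a group, with 15 of 19 members above wild type. The list shift was 0.16 (camera adjusted p = 0.00861, and adjusted p = 0.605 with an estimated correlation). Slc2a1, the glucose transporter GLUT1, gave 1495 ± 187 in wild type and 1845 ± 96.3 in mutants, and the hexokinase gene Hk2 gave 773 ± 57.2 and 996 ± 170. Tpi1 gave 5294 ± 230 and 6168 ± 634, whereas Pkm, at 6966 ± 196 and 6687 ± 664, and Pgk1, with a log2 difference of 0.03 (SE 0.10), were close to wild type. Adjusted over the list alone, 0 members passed. The call was lost without wild-type replicate 3 (adjusted p = 0.0924), without mutant replicate 3 (0.160) and with the 18S covariate (shift 0.16, adjusted p = 0.156).

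Markers of other cells in the dissected tissue did not pass the threshold with the settings used throughout, and 4 of these lists passed it under other settings. Crest and arch mesenchyme had a shift of -0.08 (camera adjusted p = 0.127), with Twist1 at 1100 ± 150 and 868 ± 71.2 and the endothelin gene Edn1 at 35.3 ± 22.2 and 90.4 ± 10.9. Erythroid genes, 10 of 15 higher in mutants, had a shift of 0.09 (0.133), with the embryonic globin Hbb-bh1 at 10776 ± 958 in wild type and 12268 ± 1069 in mutants. Hemgn, the erythroid member of smallest p, went the other way, at 329 ± 43.0 and 235 ± 36.3. Macrophage and leukocyte genes had -0.13 (0.133), cartilage and matrix genes -0.05 (0.157), and cranial sensory ganglia -0.08 (0.157). The otic vesicle list had -0.08 (0.233), Schwann and crest glia -0.06 (0.492), endothelium -0.04 (0.613) and surface ectoderm -0.01 (0.849). Muscle genes had a mean shift of 0.07 and a median log2 difference of -0.02, which differ in sign (0.492). Leaving out the dimmest probe sets took the crest and arch mesenchyme, otic vesicle and sensory ganglion lists past the threshold, all lower in mutants (adjusted p = 0.0317, 0.0230 and 0.0317). The crest and arch list also passed without wild-type replicate 1 (0.0169), but its shift turned to 0.02 with the 18S covariate and to 0.05 without wild-type replicates 2 and 3, where 1 wild-type array is left. The macrophage list, lower in mutants, passed without mutant replicate 1 (0.0387) or 2 (0.0461). Its scores on the mutant arrays were -0.03, -0.06 and -0.29, so its shift rests mostly on mutant replicate 3. That shift ran from -0.19 to -0.05 over the settings tried. Over 20 settings the adjusted p of these 4 lists reached 0.948, 0.818, 0.818 and 0.740 at the highest.

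Genes of the signalling pathways that pattern the hindbrain did not pass either, although retinoic acid genes came nearest. Of 19 retinoic acid genes 18 were lower in mutants, with a shift of -0.15 (camera adjusted p = 0.0669, and adjusted p = 0.605 with an estimated correlation). The receptor genes Rara and Rarg gave 234 ± 77.5 and 688 ± 83.2 in wild type and 149 ± 12.7 and 565 ± 75.6 in mutants, and Rxra, in the other direction, gave 434 ± 74.2 and 574 ± 83.6. This list passed under 4 settings, quantile normalization (adjusted p = 0.0376), variance trend (0.0458), leaving out wild-type replicate 1 (0.0191) and the mean of all probe sets (0.0437), in a range of 0.0191 to 0.622 over 20 settings. Notch genes, 19 of 22 lower, had a shift of -0.08 (0.126) and also passed under 4 settings, the low filter (0.0493), variance trend (0.0412), and leaving out wild-type replicate 2 (0.0221) or mutant replicate 2 (0.0461), in a range of 0.0221 to 0.605. The Notch shift ran from -0.14 to -0.02 over these 20 settings, with scores on the wild-type arrays of -0.01, -0.11 and 0.12. Wnt genes had a shift of -0.07 (0.157), hedgehog genes -0.10 (0.200) and FGF signalling genes 0.03 (0.613). In the Wnt list, Tcf7l1 gave 694 ± 15.6 and 511 ± 32.9, and Sfrp2 gave 2635 ± 503 and 1805 ± 206. Cell cycle genes had a shift of 0.07 (0.127), with 20 of 31 higher in mutants, and their median lay at percentile 45.1 among random lists matched on mean intensity. They passed without mutant replicate 1 (0.0387) and with the mean of all probe sets (0.0437), in a range of 0.0387 to 0.629. Of them, Ccnd1 gave 4200 ± 266 and 3392 ± 213 and Rrm1 3659 ± 340 and 4446 ± 189.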

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

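Control probe sets stand outside the comparison of the report, and 1 of the 64 was higher in every mutant array and over 2-fold higher in the mean. The middle probe set for the Bacillus subtilis control PheX gave 7.89 ± 6.64 in mutants and 3.11 ± 0.247 in wild type (n = 3), below the median of the bacterial controls of 12.7. Chance would place 3.2 of the 64 in each direction; 1 was higher in every mutant array, and 9 were lower in every mutant array. No explanation was tested for it.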

How the results depend on the processing

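Hoxb1 was lower in mutants under all 16 settings tried, with log2 differences from -3.13 to -2.12. It passed the threshold with array medians centred (-2.73), with the dimmest probe sets left out (-2.78), with trend and robust settings (-2.78) and with array weights (-2.83), at adjusted p of 0.0413, 0.0114, 0.0136 and 0.0496, in a range of 0.0114 to 0.743. Against 0 probe sets past the threshold as reported, quantile normalization gave 3, all higher in mutants, median centring 4 (3 higher, 1 lower), the low filter 2 (1 higher, 1 lower), trend and robust settings 3 (2 higher, 1 lower), array weights 4 (3 higher, 1 lower) and a threshold of adjusted p 0.1 gave 4. Paip1 passed under each of the first 5, and Retsat and Efcab2 under quantile normalization, centring and weights. Leaving out each array in turn gave 0 probe sets each time, as did pseudocounts of 1 and 64, 1 probe set per gene and a 1.5-fold minimum. The low filter tests fewer probe sets, but the unadjusted limma p of Hoxb1 also fell under it, from 1.23e-05 to 1.51e-06. Fewer tests are therefore not the whole cause, and the causes of these differences were not tested. The gene lists past the threshold, 6 as reported, numbered 10 with the low filter, 2 with members of 1 list only and 0 with an estimated correlation. In fry, which tests a list against no change rather than against other genes, 0 passed. Leaving out each array in turn gave 1 to 8 lists, 1 being reached without wild-type replicate 3 and without mutant replicate 3. With the 18S covariate and without wild-type replicates 2 and 3, both chosen after seeing the data, 0 lists passed. The second leaves 1 wild-type array, assumed to vary like the mutants, so it says little of stability; it gave the highest Hoxb1 adjusted p, 0.743 against at most 0.638 otherwise, and list shifts of -0.20 for rhombomere 4, -0.18 for motor neurons, -0.10 for facial migration, -0.11 for pan-neuronal genes, -0.07 for progenitors and 0.16 for glycolysis. Leaving out arrays or adding a covariate leaves fewer degrees of freedom. The members left in 1 list only were too few to test the rhombomere 4 list. A change of sign was counted as a reversal where the unadjusted p was under 0.05 under either setting. The crest and arch mesenchyme shift then reversed to 0.020 with the 18S covariate and to 0.0464 without both arrays, the latter resting on 1 wild-type array. The GABAergic, glutamatergic and glycinergic shift ran from -0.177 to 0.00458 without each array in turn, its reversal coming without wild-type replicate 3. The cause was not tested. Named probe sets kept their sign in 1938 of 1975 comparisons, and list shifts in 647 of 698, of which 42 lost and 17 gained a call. Some of these comparisons could not change a sign, so the counts overstate stability. The low filter, trend and robust settings, the block and 1 probe set per gene leave the difference of a probe set unaltered. Median centring, trend and robust settings, the block, the estimated correlation and fry leave a list shift unaltered. Whether the replicate numbers pair the arrays is left open. The sample codes share numbers between groups, and no label says whether these mark a shared day or litter. Deviations of same-numbered arrays correlated at 0.05, -0.02 and 0.04. With 3 arrays of the other group to match, 4 of 6 arrays correlated best with their own number, and these are too few to decide. With the replicate block, 0 probe sets passed (1361 at an unadjusted p under 0.05), and 6 lists. Signal over background limits dim genes, since 38.3% of probe sets had a mean below the highest bacterial control value.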

Other observations

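Transcripts of the inactive X chromosome and of the Y chromosome were measured in every pool. Xist, transcribed from the inactive X chromosome, gave 2040 ± 1166 in wild type and 2413 ± 548 in mutants (n = 3), and the Y-linked genes Kdm5d, Eif2s3y and Uty gave 226 ± 36.7, 154 ± 40.3 and 157 ± 25.5 in wild type and 176 ± 39.0, 139 ± 18.7 and 150 ± 36.8 in mutants. Wild-type replicate 3 had the highest Xist value, 3355, and the lowest Eif2s3y value, 111, of the 6 arrays. The 4 sex-linked genes had a list shift of -0.01 and camera adjusted p = 0.745.

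Genes of stress and tissue dissociation and of the p53 pathway did not pass the threshold as groups. The stress list had a shift of 0.02 (camera adjusted p = 0.695), with Hmox1 at 171 ± 13.2 in wild type and 115 ± 29.3 in mutants and Trib3 at 95.4 ± 8.13 and 65.6 ± 15.7. The p53 and apoptosis list had a shift of 0.00 (adjusted p = 0.862), and its shift and its test differed in sign. Genes next to Hoxb1 had a shift of -0.06 (adjusted p = 0.440). Npepps gave 847 ± 56.5 and 670 ± 103, and Hoxb3 gave 189 ± 34.4 and 110 ± 19.9.

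In this part quantile normalization and the camera tests of the lists, with a preset and an estimated correlation, were fixed in advance; the other tests (splits, neural genes and other tissues, other probe sets, chromosome, 18S covariate and neighbours) were chosen after the results they bear on had been seen. With 6 arrays in groups of 3 there are 10 splits, too few for a share under 0.05. For probe sets past the threshold the comparison tells nothing, since each of the 10 splits must give at least the real 0; the highest of the others gave 1. At an unadjusted p under 0.05 the real split gave 1303 probe sets and the highest other split 1941.

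The rhombomere 4 list score was lower on every mutant array than on every wild-type array, with 13 of 16 members lower in the mean and 0 past the threshold over all probe sets (camera adjusted p = 0.00175, and adjusted p = 0.425 with an estimated correlation). An offset between bright and dim genes on the mutant arrays is argued against, since quantile normalization, which removes such offsets, left the list shift at -0.31, against a wild-type SD of 0.11. A lower share of neural tissue in the mutant pools cannot be told apart from a change within that tissue: relative to 54 pan-neuronal and progenitor genes the 15 list members outside those lists (without Neurod4) were at -0.16, with SDs of 0.11 in wild type and 0.16 in mutants, and 2 of 10 lists of other tissues were higher, the others lower. Only the real split gave a list p as small (1 of 10; 5e-05, the lowest other being 0.0173), and the splits are too few to go further. A dependence of these genes on Hoxb1 may remain as a hypothesis, but no test here sets it apart from the tissue share or from the 18S signal, with which as a covariate the shift was -0.23 (adjusted p = 0.156).

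In Paip1, Retsat and Efcab2, picked for their small p, 1 probe set was higher in mutants while the other differed less, at 0.30 (SE 0.12), -0.06 (SE 0.19) and -0.07 (SE 0.18). A rise of the whole Paip1 transcript by as much is argued against. The other probe set plus 2 standard errors came to 0.535, below 1.23, which is 0.5 of the lower bound of the log2 difference. That bound comes from a probe set picked for its small p, which can inflate it, and a smaller rise of the whole transcript stays open. For Retsat and Efcab2 such a rise cannot be told apart from other explanations, since 0 of their 2 probe sets lay above the bacterial 95th percentile on any array. Chromosomal DNA carried along with the targeted Hoxb1 allele is also argued against for these genes, since 0 of the 3 lie on the chromosome of Hoxb1. Other genes higher in mutants, Pttg1 among them, were not part of this check, and DNA carried along with the allele stays open for them. Only the real split gave as many as 3 probe sets past adjusted p 0.1 in 1 direction (1 of 10, the highest other giving 1), and the splits are too few to go further. A change of 1 transcript form, or a sequence difference elsewhere in the genome between the mutant and wild-type stocks, may account for such differences between probe sets; neither was tested.

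The number of gene lists past the threshold was 6, and 2 of the 10 splits gave as many, the highest other split giving 7. The splits are too few to go further. The 18S ribosomal RNA signal cannot be told apart from the groups: with it as a covariate 0 lists passed, although the 6 shifts kept 63.99% to 95.3% of their size, from -0.32 to -0.23 for rhombomere 4, from -0.14 to -0.12 for pan-neuronal genes and 0.16 both times for glycolysis, with wild-type SDs of 0.11, 0.16 and 0.05. The adjusted p of these 3 lists became 0.156, in a fit with fewer degrees of freedom and a covariate that was low on all mutant arrays. A difference in tissue or metabolic state between genotypes may also remain, and was not tested beyond the lists.

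Chromosomal DNA next to the targeted allele may also alter neighbouring genes. Of the 100 measured genes nearest to Hoxb1, 8 had an unadjusted p under 0.05, or 8.0%, against 5.43% of other genes (Fisher's exact test, 2-sided p = 0.263), which does not decide.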
